A study of Homo sapiens with 6 samples.

How the data were processed

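The series holds sequencing of nuclease-protected RNA from purified FLAG-Rbfox1 complexes of HEK293 Flp-In cells with Rbfox2 knocked out. Per the labels, 3 samples carried Rbfox1 WT, 2 carried Rbfox1 F125A and 1 carried no transgene. Samples were grouped by the genotype named in their labels. Per the labels' protocols, a linker was ligated to the RNA, reverse transcription primers carried 4-nt molecular identifiers, cDNA with inserts of 20 to 80 nt was selected, circularised and linearised, and libraries were amplified by PCR. Per the submitters' processing notes, cutadapt and STAR were used with the hg38 build, and their versions were not given in the sources used here. The cluster caller, its threshold, the use of the control library and the gene annotation were likewise not given in the sources used here.

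The deposited data used here were 2 lists, 1 for each Rbfox1 group, which the labels name for every sample of the group. How the libraries of a group were combined was not given in the sources used here. Per the file headers, each row gives chromosome, start, end, gene, region and strand. The lists hold no read count, score or p-value, so the only measurements are the place, length, strand and gene of a cluster, and the values have no unit other than nt. Starts were read as 0-based and are printed 1-based. Of the per-sample columns, none was left unused, because the lists have none. The control sample was not analysed here.

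The WT list held 373458 rows, of which 7029 repeated an earlier row and were dropped, and the F125A list 192878 rows with 4851 repeats. A stretch of 5433 rows was word for word the same in both lists and held 3249 different clusters, 0.89% of the WT and 1.73% of the F125A clusters. It included all 3052 clusters whose gene field named several genes, and single-gene clusters of MATR3, TBCE, PINX1, HERC3, MKKS and ST6GALNAC6. The stretch was kept in the main values and left out in an alternative. Clusters naming several genes counted in the list totals and not in the table of genes. Gene names were matched to protein-coding genes of NCBI RefSeq's GRCh38.p14 table by symbol (11720 names) or by a synonym that 1 gene has (79 names), and 6 names had no match. Of the matched clusters, 99.99% in each list lay inside their gene's bounds. Gene places and lengths come from that table, which was used without exon positions.

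Overlap was taken on the same strand with at least 1 nt shared, and shares carry exact (Clopper-Pearson) 95% intervals. Random placement drew, 1000 times, a start for each F125A cluster within its gene, exons included, or within 5 kb of its place for the 3063 clusters without a single matched gene. The log2 ratio of a gene was that of WT clusters + 1 to F125A clusters + 1, minus the log2 ratio of the list totals (0.96). It was used for genes with at least 20 clusters in both lists together. Its interval comes from the exact binomial interval of the WT share, without the added 1. It treats clusters as independent, although most F125A clusters overlapped a WT cluster. Medians of gene lists have intervals from order statistics. They are set against 10000 random lists of the same size matched on total clusters in 20 bins and, as a choice made after seeing the data, on total clusters and gene length in 8 bins each. Lists with under 5 tested genes have no median. Similar length means the same of 20 bins of gene length. No test was run on reads, since the lists give no counts of reads per library, and no p-value is given for a difference of conditions. The permutation test of the overlap, and Fisher's exact test of cluster counts in the 5' and 3' parts of genes, compare the lists.

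Comparisons, 8 gene lists, the rule for named genes and part of the alternatives were fixed before the data were examined. The rule names up to 4 members of each list, the 10 genes with most clusters in each list, the 10 highest and 10 lowest ratios, and the 10 genes with most WT clusters that overlap no F125A cluster. It had been written with the pentamer bound by Rbfox and a score per cluster in mind. Without the genome sequence, not used here, and without scores, list members were ordered by WT clusters and the parts on the pentamer and on the highest scores were left out. Planned results on sequence motifs, splice-site distance and cluster score were left out for the same reasons, and the distance to the annotated gene start and end was added. Values of some single genes of the lists are not reported here. Alternatives fixed beforehand covered merging of clusters closer than 50 nt for their number and size, the overlap rule, local placement, an added 5 and a minimum of 10 clusters. Chosen after seeing the data were merging for the gene ratios, dropping the identical stretch, keeping repeats, centring on the median gene and correcting for gene length.

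The statistics were tested on simulated data, in which the clusters of each gene were divided independently between the lists. With 200 of the 5626 genes changed by known folds, the 2-fold rule recovered 94.0% of genes raised 4-fold, 100.0% of those lowered 4-fold, 98.0% of those raised 8-fold and 100.0% of those lowered 8-fold, and it took in 2.8% of the 5426 unchanged genes. The overlap counts equalled those of bedtools 2.31.1, with 160798 F125A and 165536 WT clusters. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.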

Results

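RNA that stayed protected from nuclease was sequenced from complexes of FLAG-tagged Rbfox1, a splicing regulator, with LASR, a large assembly of other RNA-binding splicing proteins. The complexes were purified from HEK293 Flp-In cells, a human embryonic kidney line with a single site for inserting a transgene, in which Rbfox2 had been knocked out (clone 7). There were 3 libraries with wild-type Rbfox1 (WT), 2 with Rbfox1 F125A, which replaces a phenylalanine of the RNA recognition motif, and 1 from cells with no transgene. For each Rbfox1 group there was 1 list of clusters, places covered by sequenced RNA, in the introns of protein-coding genes on hg38. The control library was not analysed here, so background recovered without a FLAG-tagged protein was not subtracted here. Whether it had been removed from the lists was not given in the sources used here. The comparison asks which intronic places were recovered with each form of Rbfox1. Because each list stands for its whole group, no value has a replicate error, and the intervals given cover counting error only. Read depth is unknown, because the lists hold places and no read counts or scores.

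The WT list held 366429 different clusters and the F125A list 188027, that is 1.95 WT clusters for each F125A cluster. They covered 23.6 Mb and 12.9 Mb of transcribed strand. Clusters were short in both lists: the median length was 60 nt in the WT list, with quartiles of 48 and 76 nt, and 64 nt in the F125A list, with quartiles of 50 and 82 nt. F125A clusters had the longer median on all 23 chromosomes other than Y, which held 1 cluster in each list and is left out of the ranges between chromosomes. The plus strand held 52.4% of WT clusters (exact 95% interval 52.2 to 52.6%) and 52.0% of F125A clusters (51.8 to 52.3%). On the 23 chromosomes other than Y, WT clusters per F125A cluster ranged from 1.51 on chromosome 19 to 2.26 on chromosome 18. The WT list rests on 3 libraries and the F125A list on 2, so the list totals alone do not compare the proteins.

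Most places found with F125A were also found with WT. Of the F125A clusters, 160798 overlapped a WT cluster on the same strand by at least 1 nt, a share of 85.5% (exact 95% interval 85.4 to 85.7%), and between the 23 chromosomes other than Y this share ranged from 82.4% to 87.5%. In the other direction, 165536 WT clusters, or 45.2% (45.0 to 45.3%), overlapped an F125A cluster, which left 200893 WT clusters and 27229 F125A clusters without a partner. The shorter F125A list by itself limits how many WT clusters can have a partner, so those without one are not shown to be lost with F125A. By chromosome the WT share ranged from 38.7% on chromosome 18, with 2.26 WT clusters per F125A cluster, to 58.9% on chromosome 19, with 1.51. When F125A clusters of the same lengths were placed at random within the same genes, a mean of 10.1% overlapped a WT cluster and the most in any of 1000 placements was 10.4%. The observed overlap was 8.45 times the random mean (one-sided permutation p = 0.001, the smallest that 1000 placements can give), a comparison of the 2 lists and not of the conditions. WT clusters without a partner were shorter (median 57 nt) than WT clusters with one (63 nt), whereas F125A clusters without a partner were longer (68 nt against 63 nt).

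Both forms of Rbfox1 recovered clusters from largely the same genes, and long genes held the most. Of 11805 genes named alone in at least 1 list, 10406 had clusters in both, 1145 in the WT list only and 254 in the F125A list only. Most genes found in 1 list only had few clusters: the median was 1 for those with WT clusters only, although STK32C had 32, and none of those with F125A clusters only had more than 4. AUTS2 on chromosome 7 had the most in each list, with 1463 WT and 631 F125A clusters. In the WT list it was followed by PRKG1 (932), a cGMP-dependent protein kinase, ERBB4 (913), a receptor tyrosine kinase, SLIT2 (903), an axon guidance ligand, TTC28 (800), PTPRG (776), a receptor phosphatase, FHIT (710), WWOX (710), SDK1 (706) and PARD3 (698), a cell polarity protein. Of these, 8 were also among the 10 genes with most F125A clusters, where TTC28 had 495, SLIT2 476, ERBB4 414, PRKG1 408, PTPRG 375, SDK1 357 and FHIT 341, and where ERC1 (398) and IMMP2L (367) took the remaining places. WT clusters that overlapped no F125A cluster were most numerous in AUTS2 (831), PRKG1 (540), ERBB4 (528), WWOX (419), SLIT2 (418), FHIT (411), PTPRG (411), PARD3 (399), MECOM (372), a zinc finger transcription factor, and SDK1 (364). All but MECOM were also among the 10 genes with most WT clusters, so this order largely follows the number of WT clusters. Over the whole list, 200893 of 366429 WT clusters overlapped no F125A cluster.

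Relative to the list totals, few genes leaned strongly to either protein. For the 5626 genes with at least 20 clusters in both lists together, the log2 ratio of WT to F125A clusters, with 1 added to each and the log2 ratio of the list totals subtracted, had a median of -0.04 and quartiles of -0.36 and 0.26. A ratio of 0 thus stands for 1.95 WT clusters per F125A cluster. In 141 genes the ratio lay 2-fold or more toward WT, in 112 genes 2-fold or more toward F125A, and in 5373 genes (95.5%) between these bounds. In simulated data, with clusters divided independently between the lists, the same rule took in 2.8% of unchanged genes. In the real lists 85.5% of F125A clusters overlapped a WT cluster, so the 2.8% need not be their counting error. How many of these genes differ is therefore unknown, and many may not. With 5 in place of 1 added, 36 genes lay 2-fold or more toward WT and 112 toward F125A. No test of conditions was possible with 1 list per group, and genes were named by size of the ratio.

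The genes with the highest ratios had WT clusters and almost none with F125A. STK32C, a serine/threonine kinase gene on chromosome 10 (132207482 to 132332235), had 32 WT clusters and no F125A cluster, and CHRM3, the M3 muscarinic receptor gene on chromosome 1 (239386568 to 239915450), had 20 and none. PRR16 on chromosome 5 (120464278 to 120794594) had 50 WT clusters and 1 F125A cluster, a log2 ratio of 3.71 (exact binomial interval 2.14 to 10.01). GRIK3, a kainate receptor subunit, had 25 and 1 (2.74, interval 1.07 to 9.04). CSRNP3 had 23 and 1 (2.62, 0.94 to 8.93), GPC5, a glypican, 47 and 3 (2.62, 1.37 to 5.34), and PLCL1, a phospholipase C-like protein, 19 and 1 (2.36, 0.63 to 8.66). TNFRSF21, a death receptor, had 27 and 2 (2.26, 0.80 to 5.91), CPQ, a carboxypeptidase, 26 and 2 (2.21, 0.74 to 5.86), and GPR176, an orphan receptor, 33 and 3 (2.12, 0.82 to 4.85). With 5 added in place of 1, the 10 ratios ranged from 1.04 to 2.23.

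The genes with the lowest ratios were at most 19.9 kb long, and 4 of the 10 encode ribosomal proteins or a protein bound to the ribosome. NCL, which encodes nucleolin, had 7 WT and 17 F125A clusters (log2 ratio -2.13, interval -3.75 to -0.90). The ribosomal protein genes RPL4 (8 and 15, -1.79, interval -3.31 to -0.54), RPL3 (11 and 18, -1.63, -2.90 to -0.51) and RPS12 (10 and 16, -1.59, -2.94 to -0.41) also had more F125A than WT clusters, as did RACK1, a ribosome-associated scaffold (9 and 16, -1.73, -3.15 to -0.53). The others were FASN, the fatty acid synthase (17 and 27, -1.60), SCML1 (36 and 56, -1.59), IRS4, an insulin receptor substrate (48 and 74, -1.58), HMGN1, a nucleosome-binding protein (21 and 32, -1.55), and TCP1, a chaperonin subunit (9 and 14, -1.55). All 10 had more F125A than WT clusters although the F125A list was the shorter. With clusters closer than 50 nt merged, RPL4 and RPS12 had under 20 clusters and were not tested, and IRS4 moved to -1.03, RPL3 to -1.16, RACK1 to -1.18, SCML1 to -1.18 and HMGN1 to -0.39. Relative to genes of similar length, 6 of the 10 stayed 2-fold or more toward F125A, and RPL3, RPS12, HMGN1 and TCP1 lay between -0.90 and -0.83.

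**Figure D1:**
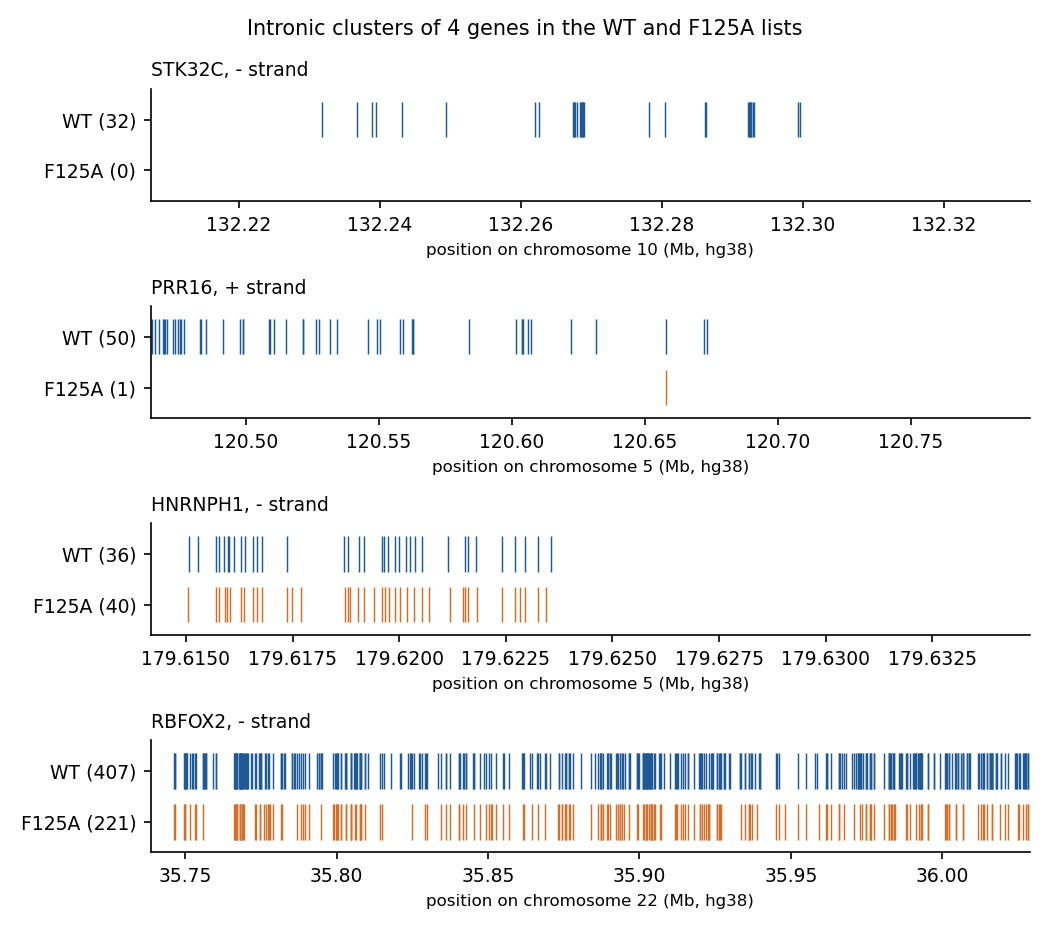
Clusters of STK32C, PRR16, HNRNPH1 and RBFOX2 by position in Mb on hg38, each vertical line the midpoint of 1 cluster, with WT in the upper and F125A in the lower line of each panel and the number of clusters in parentheses. STK32C had 32 WT clusters and no F125A cluster, whereas HNRNPH1 had 36 and 40, mostly at the same places.

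Relative to the list totals, the genes of the complex itself and of other splicing regulators leaned to F125A, but less so with gene length corrected. The transcripts of the LASR subunits had a median log2 ratio of -0.77 over the 6 with at least 20 clusters (interval of the median -1.23 to 0.02), and 5 of the 6 lay below 0. HNRNPC had 146 WT and 103 F125A clusters (-0.46), MATR3 104 and 102 (-0.93) and HNRNPM 76 and 38 (0.02). HNRNPH1 (36 and 40, -1.11) and ILF2 (9 and 11, -1.23, interval -2.70 to 0.16), chosen after their values were seen, lay 2-fold or more toward F125A, but at -0.63 and -0.50 relative to genes of similar length. For MATR3, 80 clusters in each list belonged to a stretch of rows identical in both lists, and 24 WT and 22 F125A clusters lay outside it. Among the other splicing regulators, 26 of 30 tested genes lay below 0 and 4 above, with a median of -0.61 (interval -0.78 to -0.31). CELF2 (232 and 96, 0.30), QKI (213 and 100, 0.12) and MBNL1 (158 and 63, 0.35) lay above 0 and CELF1 (110 and 70, -0.32) below, but relative to genes of similar length CELF2 lay at -0.12, QKI at -0.01 and MBNL1 at 0.14. SRSF6 (25 and 27, -1.07) lay 2-fold or more toward F125A and PTBP3 (43 and 9, 1.17) 2-fold or more toward WT, both also chosen after their values were seen, and with gene length corrected they lay at -0.35 and 1.04. Against 10000 random lists with the same numbers of clusters per gene, both medians lay at percentile 0.0. Matched on gene length as well, the medians of the random lists themselves centred on -0.46 and -0.45, so much of the lean goes with length. The list medians then lay at percentile 1.9 for the LASR subunits and 2.1 for the splicing regulators. These percentiles were matched in 8 bins of length and can still hold part of the trend with length. After subtracting the median of genes of similar length, in 20 bins, the list medians were -0.45 and -0.14.

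Genes with exons known to be regulated by Rbfox proteins had a median ratio near 0, as RBFOX2 did. The ratio counts all intronic clusters of a gene relative to the list totals, so a loss common to all genes would not show. Clusters near the regulated exons or with the pentamer bound by Rbfox were not examined. A ratio near 0 therefore does not say that F125A kept those sites. RBFOX2, the gene knocked out in these cells, still had 407 WT and 221 F125A clusters in its introns (-0.08, interval -0.32 to 0.16), RBFOX3 had 20 and 9 (0.11, -1.01 to 1.51), and RBFOX1, whose product was supplied by the transgene, 4 and 3. The knockout was common to both lines, so these values do not check it. Of 22 genes listed for Rbfox-regulated exons, 21 had a cluster and 20 were tested, 10 above and 10 below 0, with a median of -0.02 (interval -0.34 to 0.17) at percentile 37.7, or -0.10 relative to genes of similar length and percentile 13.6 with gene length matched. ENAH, an actin regulator, had 274 WT and 178 F125A clusters (-0.34, interval -0.62 to -0.06), PTBP2 244 and 156 (-0.32, -0.61 to -0.02), CAMTA1 138 and 73 (-0.05) and CACNA1C, a calcium channel, 120 and 40 (0.60, 0.10 to 1.18). FMNL3 (15 and 17, -1.13), chosen after its value was seen, lay 2-fold or more toward F125A, also relative to genes of similar length (-1.07). The same correction put RBFOX2 at -0.40, below its counting interval, RBFOX3 at -0.31, ENAH at -0.47, PTBP2 at -0.36, CAMTA1 at -0.48 and CACNA1C at 0.18.

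Actin and adhesion genes, motor genes and chromatin regulators differed little from 0. Of 24 actin and adhesion genes, 17 lay above and 7 below 0, with a median of 0.21 (interval -0.07 to 0.34) at percentile 98.5, or 96.6 with gene length matched, but the median was 0.01 relative to genes of similar length. TRIO had 461 WT and 247 F125A clusters (-0.07), PTK2, the focal adhesion kinase, 315 and 182 (-0.17), DST 293 and 129 (0.21) and AFDN 278 and 159 (-0.16). TLN2, a talin chosen after its value was seen, was the only 1 of the 24 at 2-fold or more, with 42 and 8 (1.29). Of 15 kinesins and other microtubule genes, 12 lay above and 3 below 0, with a median of 0.12 (interval 0.04 to 0.25), which turned to -0.03 relative to genes of similar length. CLASP1 had 188 and 87 (0.14), CLASP2 170 and 80 (0.12), MACF1 136 and 56 (0.30) and MAP4 121 and 58 (0.09). DYNC1I2, a dynein intermediate chain chosen after its value was seen, had 78 and 10 (1.88, interval 1.05 to 3.12). The 24 chromatin regulators, with 11 above and 13 below 0 and a median of -0.03 (interval -0.12 to 0.10), held none at 2-fold or more in either direction, and their median was -0.11 relative to genes of similar length. Among them ARID1B had 561 and 246 (0.22), KMT2C 269 and 142 (-0.05), JARID2 268 and 134 (0.03) and EHMT1 244 and 143 (-0.20). Relative to genes of similar length, DST (-0.21), CLASP1 (-0.17), CLASP2 (-0.09), MACF1 (-0.01), MAP4 (-0.12), ARID1B (-0.20) and JARID2 (-0.28) lay below 0, TRIO (-0.38), PTK2 (-0.49), AFDN (-0.29), KMT2C (-0.36) and EHMT1 (-0.40) further below, TLN2 at 0.87 and DYNC1I2 at 1.95. Of 16 genes characteristic of liver, blood, muscle or neurons, 7 had any cluster, and only DMD, with 21 and 11, had enough to be tested (-0.09, or -0.51 relative to genes of similar length).

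**Figure D2:**
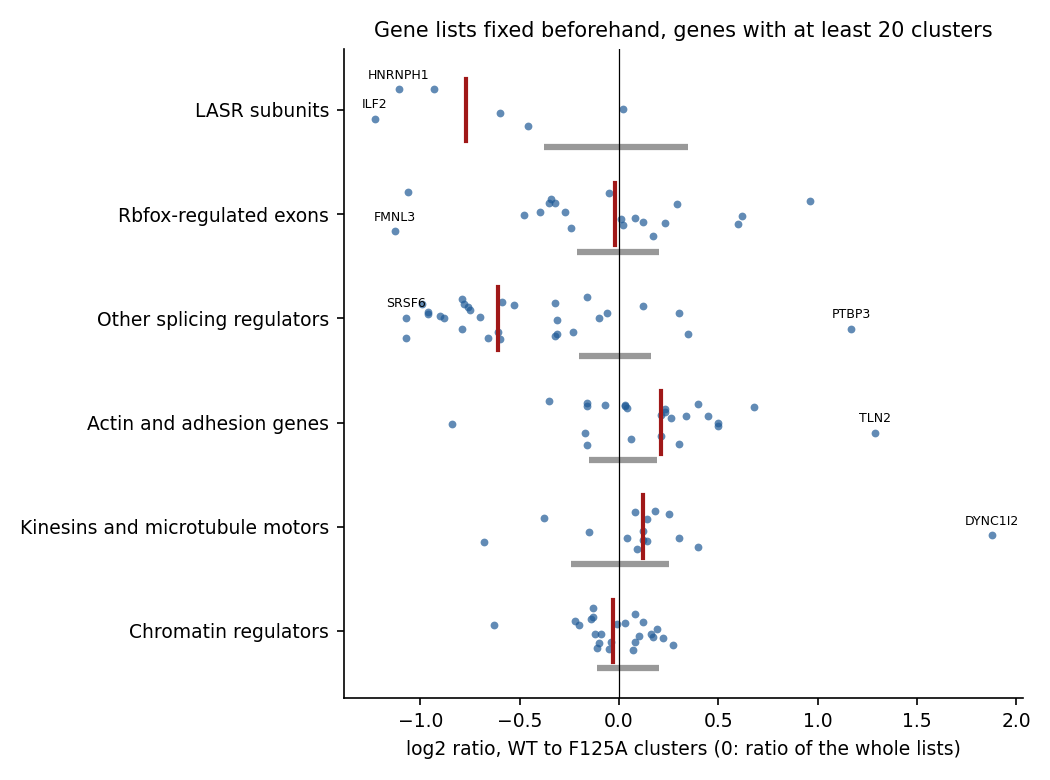
Log2 ratio of WT to F125A clusters for the members of 6 gene lists with at least 20 clusters, each point 1 gene, with 0 at the ratio of the whole lists. Red lines are list medians and grey bars the central 95% of medians of 10000 random lists matched on clusters per gene, and the medians of the LASR subunits (-0.77) and other splicing regulators (-0.61) lie below their bars. The median of the actin and adhesion genes (0.21) lies above its bar, which ends at 0.19.

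The ratio was higher in longer genes. The decile of genes with the shortest annotated length, 2.47 to 21.9 kb, had a median log2 ratio of -0.61 (interval -0.64 to -0.57), and the decile with the longest, 273 to 2299 kb, 0.38 (0.34 to 0.42). The shortest decile held 67 of the 112 genes that lay 2-fold or more toward F125A and no gene 2-fold or more toward WT, whereas the longest decile held 52 of the 141 toward WT and none toward F125A. Spearman's rho between ratio and length was 0.57 across the 5626 genes, which are not independent replicates. After subtracting the median of genes of similar length, 115 genes lay 2-fold or more toward WT and 26 toward F125A.

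**Figure D3:**
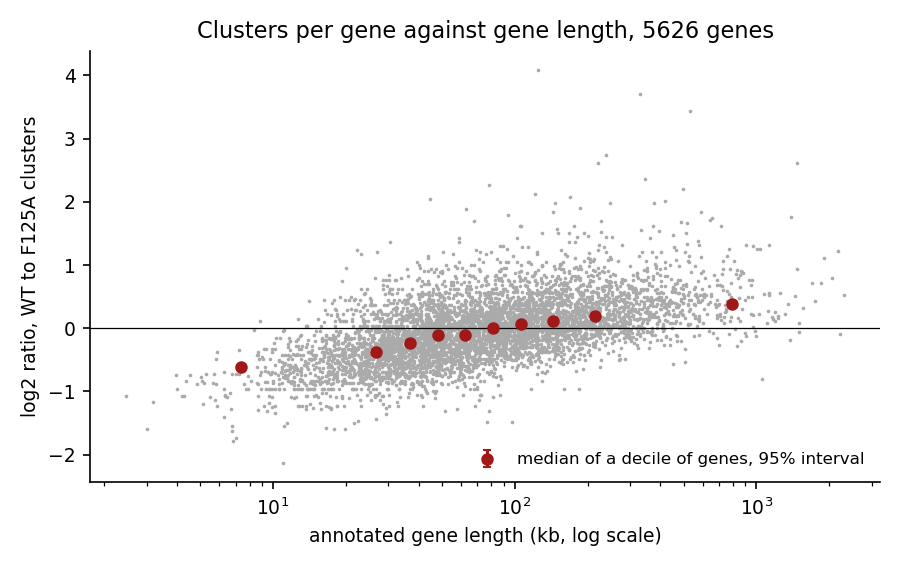
Log2 ratio of WT to F125A clusters (vertical) against annotated gene length in kb (horizontal, log scale) for 5626 genes, each grey point 1 gene. Red points are medians of deciles of the genes with 95% intervals, and they rise from -0.61 to 0.38.

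A larger share of F125A than of WT clusters lay near the start of the gene, and also near its end. Within 1 kb of the annotated gene start there were 6226 F125A clusters, 3.37% of those in genes with a known place (exact interval 3.28 to 3.45%), and 7103 WT clusters, 1.95% (1.91 to 2.00%). In genes under 30 kb the shares were 12.2% with F125A and 9.41% with WT, in genes of 30 to 100 kb 3.46% and 2.23%, and in genes over 100 kb 1.09% and 0.58%. Within 5 kb of the annotated gene end lay 5.21% of F125A (5.11 to 5.32%) and 3.78% of WT clusters (3.72 to 3.84%), or 26.3% and 23.5%, 4.00% and 3.68%, and 0.64% and 0.56% in the same classes of length. The first 10% of the gene's length held 15.7% of F125A and 13.9% of WT clusters, and the last 10% held 4.56% of each. Clusters of 1 gene are not independent, so the intervals are narrower than the true error.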

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

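The alternatives without the identical stretch of rows, with repeated rows kept, with the median gene as 0, with the ratio corrected for gene length, and with merged clusters for the gene ratios were chosen after seeing the data. The share of F125A clusters that overlapped a WT cluster stayed between 84.7% and 87.5% and above random placement in every alternative run (5.44 to 12.9 times the random mean). The share of WT clusters with a partner was 44.0% when 50% of the shorter cluster had to be shared, 49.2% with partners within 50 nt and 44.7% without the stretch. WT clusters per F125A cluster came to 1.89 after merging clusters closer than 50 nt, 1.94 with repeats kept and 1.97 without the stretch, and merging raised the median lengths to 63 nt (WT) and 66 nt (F125A). Genes 2-fold or more toward WT numbered 36 with 5 added against 141, and 263 with a minimum of 10 clusters. Toward F125A they numbered 273 with that minimum against 112. After merging, 78 lay toward F125A, 55 of them among the 112, and 133 toward WT, 116 of them among the 141. Corrected for gene length, 26 genes lay toward F125A, 22 of them among the 112, and 81.6% of the 2-fold genes lay toward WT against 55.7% without the correction; gene length is what that alternative removes. The same correction moved the median of the splicing regulators to -0.14 and that of the motor genes to -0.03, the only list that changed sign among those whose interval excluded 0. The Rbfox-regulated genes and the chromatin regulators, whose intervals span 0, had medians of 0.01 with the median gene as 0. Of 72 named genes, 22 left their counting interval under the length correction, 1 of 72 did with 5 added and 3 of 67 after merging. No paired analysis was possible because each group has 1 list and no values per library, and leave-one-out of a library was not run for the same reason. Also not run, for want of a score or of the genome sequence and intron positions in the sources used here, were all alternatives on score thresholds, list thinning and summed scores, on searched windows, repeats, 1 cluster per gene and shifted backgrounds of motifs, and on splice-site distance. Unknown read depth limits every count, since a gene without a cluster in a list can still have reads.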

Other observations

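The tests of chromosome stretches, identical ends, snoRNA and a common direction within genes were chosen after the results they measure had been seen in part, and gene families by symbol were chosen after seeing the data. Ribosomal protein genes were looked at as a family because RPL4, RPL3 and RPS12 were among the 10 lowest ratios. All 19 with at least 20 clusters had a log2 ratio below 0, with a median of -0.84 (interval -1.20 to -0.67), at percentile 0.0 of random lists matched on clusters and 0.6 with gene length (median 7.11 kb) matched too. Relative to genes of similar length, in 20 bins, the median was only -0.12. The percentiles were matched in 8 bins of length, so they can still hold part of the trend with length. Without these 3 genes the median was -0.76 over 16 genes (interval -0.90 to -0.58), or -0.09 relative to genes of similar length, at percentile 3.3 with clusters and gene length matched. Zinc finger genes named ZNF had a median of -0.23 over 158 genes, but lay at percentile 43.1 once gene length was matched, and translation initiation factor genes, with a median of -0.35 over 29 genes, lay at percentile 30.5. The 20 proteasome subunit genes, short as well with a median of 24.6 kb, lay at -0.20 and at percentile 86.8 with length matched. Of the 9 other families examined, 4 lay at percentile 8.0 or lower with length matched, among them glutamate receptors (3.1, 5 genes), collagens (4.8, 12 genes) and heterogeneous nuclear ribonucleoproteins (6.1, 16 genes).

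Of the 10 genes with the lowest ratios, 8 hold an annotated small nucleolar RNA (snoRNA) gene within their bounds: NCL, RPL4, RACK1, RPL3, FASN, RPS12, HMGN1 and TCP1. One candidate explanation was that F125A clusters there lie on mature snoRNA. Of the 155 F125A clusters in these 8 genes, 9 overlapped a snoRNA, or 5.81% with an exact upper limit of 10.7%, above the 10% first set as the bound, as did 5 of 92 WT clusters. Such clusters are argued against as the whole cause, since without them the median log2 ratio of the 8 genes was -1.62, against -1.61 with them. Without them the single genes ranged from -2.28 to -1.50. These genes had been picked for low ratios, so only the lack of change speaks to the question, and not the low level. The 317 tested host genes had a median of -0.03, against -0.04 for the other genes, but -0.05 relative to genes of similar length, at percentile 6.1 of random lists matched on clusters and gene length. Over the whole lists, 73 WT clusters (0.0199%) and 65 F125A clusters (0.0346%) overlapped a snoRNA, and 121 (0.033%) and 127 (0.0675%) a microRNA gene.

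The rise of the WT to F125A ratio with gene length (rho 0.57, bootstrap interval 0.55 to 0.59) held across deciles of length except from the fourth (median -0.10) to the fifth (-0.11). Crowding of clusters in dense genes is argued against as the whole cause, since rho within 10 strata of clusters per kb averaged 0.39 and was at least 0.27 in each. It was 0.32 in the sparsest and 0.56 in the densest stratum, so a part played by crowding stays open. The richer F125A signal near gene starts is argued against as the whole cause, since rho was 0.53 (0.51 to 0.55) without clusters within 5 kb of the start. Greater depth of the WT list stays open: with that list limited to its first rows, as many as the F125A list has, rho fell to 0.39 (0.37 to 0.42), between the bounds set beforehand, and the meaning of the row order is not stated. A difference between the proteins in the kinds of intron they hold may also contribute, and it was not tested.

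Genes 4-fold or more toward WT numbered 13, among them POLN (32 and 3), SHC2 (23 and 2) and SNTG2 (54 and 6) beside the 10 highest. With 5 added PRR16 alone stayed there (2.23) and the other 12 lay between 1.04 and 1.92, while correction for gene length put SNTG2 (1.59), CPQ (1.78) and POLN (1.89) below 4-fold. Drawing clusters by chance, with the WT share of genes of similar length, gave a mean of 1.11 and at most 7 such genes in 1000 draws, which missed the bound set beforehand (under 50% of the observed number in every draw), so chance stays open for some of the 13. The draws treated clusters as independent, although most F125A clusters overlapped a WT cluster, so their spread may not be that of the lists. Loss in the F125A line of a chromosome stretch that reaches 500 kb beyond the gene on both sides is argued against for the 12 with a tested neighbour, since their 37 neighbours (11 near POLN, 8 near SHC2) had a median log2 ratio of -0.30 (interval -0.58 to -0.17), none reached 1, and the medians per gene centred on -0.22 (interval -0.33 to 0.11). Such a loss at PRR16, with 0 tested neighbours within 500 kb, stays open, as do shorter losses at any of the 13. GPC5, 1469 kb long, had 45 WT and 1 F125A clusters in its 5' part and 2 and 2 in its 3' part. That split rests on few 3' clusters and did not pass adjustment over 5626 genes (Fisher's exact test, unadjusted p = 0.0143). A difference in transcription between the lines, possibly from clonal growth, also stays open, because no RNA level was measured.

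The stretch of rows identical in both lists was found by that identity, so the same ends of its 3249 clusters say nothing on where it came from. Elsewhere 2.26% of overlapping F125A clusters (3558 of 157549) had a WT cluster with the same ends. Calling on the F125A libraries alone cannot be decided by length. The stretch had a median of 61 nt (interval 60 to 62), against 64 nt for the other F125A and 60 nt for the other WT clusters. That interval covers counting error only, and F125A medians were also 61 nt on chromosomes 16 and 22. The stretch holds all clusters that name several genes, so no like F125A clusters are left to compare. Rows written once to both lists and pooled calling of both groups cannot be told apart, because either gives the same ends. For genes of the stretch such as MATR3 and TBCE, similar numbers of WT and F125A clusters may therefore not be a measurement (outside it, TBCE had 2 WT and no F125A clusters).

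Overlap fell along the rows of each list. Without the stretch and the rows after it, the first 10% of WT rows overlapped an F125A cluster in 70.8% and the last 10% in 15.3%, while the shares for F125A rows were 97.9% and 62.5%. Median length fell from 72 to 49 nt between the first and last 10% of WT rows and from 76 to 58 nt between those of F125A.

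A last hypothesis was that some genes change balance along their length, for example through another promoter in one line. Fisher's exact test of WT and F125A clusters in the 5' and 3' parts of each of 5626 genes, divided at the midpoint, found 0 genes at a Benjamini-Hochberg adjusted p under 0.05, while 100 shuffles of the list labels gave at most 1. The smallest unadjusted p of this exact test was 0.000562, for ERBB4, with 797 WT and 387 F125A clusters in the 5' part and 116 and 27 in the 3' part (adjusted p = 1). Each test compares the lists and not the conditions, and chance placement covers the number of single genes. Fisher's exact test also treats the clusters of the lists as separate, so 0 passing genes do not show an even balance along genes. For all genes together, the WT to F125A ratio was higher in the 3' part in 2885 genes and in the 5' part in 2651, or 52.1% against 47.4 to 51.1% in the shuffles. This argues against chance placement of independent clusters. Clusters of 1 gene are not independent, and the shuffles ignored that 85.5% of F125A clusters overlapped a WT cluster. The range may therefore be too narrow or too wide, and chance is not excluded. The first 10% of the gene held 15.7% of F125A and 13.9% of WT clusters, which are the same clusters and not separate evidence.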
